A study of Oryza sativa with 14 samples.

How the data were processed

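Small RNAs of 15-30 nt were gel purified, per the labels' protocols, from panicle and flag leaf of rice (Oryza sativa) and sequenced on the Illumina platform after Trizol extraction and enrichment with PEG and salt. Plants of 4 cultivars stood at 30 °C and 70% relative humidity. Heat was 42 °C for 6 hours, per the labels. The growth protocol speaks of flag leaf and root, whereas the source field of each sample says panicle or flag leaf. The source field was used here. The series' design text places every sample in a pair of control and heat. The pairs were taken as the libraries of 1 cultivar and 1 tissue: Shatabdi, Lalat, BPT-5206 and Nagina-22 in panicle, and Nagina-22, Lalat and BPT-5206 in flag leaf. Per the labels, Nagina-22 is heat tolerant and the other cultivars are heat susceptible. Nothing states that libraries come from separate plants or from pools, so the p-values measure only the spread between these samples.

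Each deposited file lists distinct sequences with their read counts, and these counts are raw whole numbers per the values themselves, with single reads kept and no scaling. The authors collapsed the reads to distinct sequences. Bowtie was named per the submitters' processing notes, without a role. Of the 14 files, 11 hold sequences of 5-35 nt, and 3 hold only 20-27 nt (panicle heat Shatabdi, flag leaf heat Nagina-22 and flag leaf control BPT-5206). The planned minimum of 18 nt was therefore raised to 20 nt in every library. This was a departure from the plan made after the data were examined. Total reads ran from 11392785 to 29781424 per library, and reads of 20-26 nt from 6769184 to 17398117. The library of most total reads, panicle heat Nagina-22, held 42.6% of them at 35 nt, against at most 20.5% in any other library. PCR reads without molecular identifiers are not independent molecules, so the intervals and floors given cover counting error only. Shares of a single library carry 95% Wilson intervals in the tables.

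No genome was used. A list of 86 mature rice miRNA sequences, written out from general knowledge before the data were examined, made 78 features after sequences sharing their first 17 nt were joined. Of these, 71 had reads. A miRNA's count was the number of reads of 20-25 nt that started exactly at the listed 5′ end and equalled the first 17 nt. For end classes, a read was assigned to a miRNA when its start lay within 3 nt of the listed start, at least 16 nt were templated and at most 3 nt at the 3′ end were not. A read whose last 1-3 nt differ from the listed sequence or run past its end was counted as tailed. Without a genome, nucleotides past the mature end that the precursor encodes count as tails, and reads of a related locus are not separable from modified reads. The end analysis was restricted, after the data were examined, to the 41 miRNAs whose listed sequence makes at least 50% of their assigned reads. Internal mismatches at positions 8-14, counted from 1 at the 5′ end, gave the background.

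miRNA and tag counts were compared with edgeR 4.0.16 (quasi-likelihood fits, TMM scaling, prior count 2 for displayed values) and a Benjamini-Hochberg false discovery rate of 0.05. Features were kept by filterByExpr with a minimum count of 10. Heat was tested over 7 pairs with pair as block, within each tissue, and as heat-by-tissue and heat-by-tolerance interactions. Tissue was tested in the 12 libraries of the 3 cultivars with both tissues, with cultivar and heat as terms. Tolerance was tested over all 14 libraries with tissue and heat as terms. A single cultivar is tolerant, so tolerance and genotype are not separable. A tag is a distinct sequence of 20-26 nt with at least 10 reads in at least 3 libraries, and 140024 were tested. Shares of reads per library were compared by exact two-sided sign-flip permutation tests over pairs (128 sign patterns for heat, 64 for tissue). The 6 tissue comparisons come from 3 cultivars, each in control and heat. Tailing of single miRNAs was compared with limma 3.58.1 on the log2 ratio of tailed to untailed reads with 0.5 added to each, where a library had at least 20 reads and at least 5 pairs were complete. Fixed lists (development, auxin, silencing pathway, copper, nutrient, reproductive, rice-specific, star strands and earlier heat reports) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. DESeq2 1.42.0 served as the other tool. Other software was R 4.3.3, version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

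Comparisons, lists, tests and the naming rule were fixed before the data were examined. Named were every miRNA past the threshold if 24 or fewer passed, otherwise the 12 largest rises and the 12 largest falls among miRNAs with a mean of at least 10 CPM (counts scaled to library totals); where nothing passed, the 6 of smallest p; of each list, the 3 members of highest mean CPM, whose values are given in full for heat over both tissues, for tissue and for tolerance, and as extremes for the other heat contrasts; the 5 tags of largest rise and the 5 of largest fall with a mean of at least 10 CPM; every miRNA past the tailing threshold if 20 or fewer, and the 10 miRNAs of most reads.

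Pairing was checked by the correlation of the control and heat library of a pair over miRNAs after the group means were removed. It was 0.701 for Shatabdi, 0.568 for Lalat, 0.487 for BPT-5206 and 0.397 for Nagina-22 in panicle, and 0.541 for Nagina-22, 0.562 for Lalat and 0.287 for BPT-5206 in flag leaf. Libraries of different cultivars were not correlated for reference. The panicle pair labelled BPT-5206, whose heat library carries tags of Lalat, stood above that of Nagina-22. The check therefore cannot tell right pairs from wrong ones, and pair was kept as a block because of the design text. After the mean was removed, the tissue differences of control and heat correlated over miRNAs within a cultivar at 0.08 for Nagina-22, 0.49 for Lalat and 0.03 for BPT-5206. The heat changes of panicle and flag leaf correlated within a cultivar at -0.23, 0.06 and 0.08 in the same order.

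The edgeR tests were tried on simulated counts with known changes, and the tailing test on simulated log2 ratios. Each feature was simulated around 1 mean over all libraries, without differences between pairs, cultivars or tissues beyond the changes put in. In the counts, only features with a mean of at least 10 CPM were changed. Recovery in the real libraries may therefore differ. For miRNAs under heat, 53 features were simulated: a log2 change of 1 was recovered in 3 of 4, of 1.5 in 4 of 4 and of 2 in 4 of 4, with 1 false call among 41. For miRNAs between tissues, 55 were simulated: a log2 change of 1 was recovered in 0 of 4, of 1.5 in 1 of 4 and of 2 in 4 of 4, with 0 false calls among 43. For tags under heat, 140024 were simulated: a log2 change of 2 was recovered in 24 of 100 and of 4 in 85 of 100, with 4 false calls. For tailing under heat, 25 were simulated: a log2 change of 1 was recovered in 4 of 6, with 1 false call among 19. The tag comparison between tissues, the tailing comparison between tissues and the interactions used the same procedures and had no simulation of their own. The same holds for heat within a tissue and for tolerance. Camera, fry and the sign-flip permutation tests were not simulated.

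Alternatives were DESeq2, no TMM scaling, no low-count filter, no pair block, exact mature reads alone, a stricter tag minimum of 50 reads, other length windows, other tail definitions, and leaving out each pair. Added after the data were examined were the fits without the pairs that hold a length-limited file, those counting shifted 5′ ends, and the counts without the pair whose heat library is in doubt. Tags outside 20-26 nt were not analysed here. Tags were not sorted by class of RNA, so fragments of ribosomal, transfer and chloroplast RNA are not separable from small RNAs among them.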

Results

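Small RNA reads were measured in 14 libraries of rice panicle, the flowering head, and flag leaf, the last leaf below it, under control and heat. There were 4 panicle control, 4 panicle heat, 3 flag leaf control and 3 flag leaf heat libraries, which form 7 pairs of 1 cultivar and 1 tissue each. Total reads ran from 11392785 to 29781424 per library, and listed miRNAs made 3.11% to 7.44% of the reads of 20-26 nt. Over all tested miRNAs the first principal component held 70.8% of the variance and set panicle libraries (-11.1 to -7.24) apart from flag leaf libraries (9.78 to 13.1). The library labelled panicle heat BPT-5206 carried 99.3% of 970 tags found in flag leaf of Lalat alone and 0.526% of 380 tags found in flag leaf of BPT-5206 alone. Numbers of calls without its pair are therefore given for most comparisons. Most permutation tests of shares, those of the tag family and of miR168a-5p ends, and the fitted fold changes keep this pair as labelled. A pair of flag leaf libraries, control Nagina-22 and heat BPT-5206, carried altered first nucleotides on many reads.

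**Figure D1:**
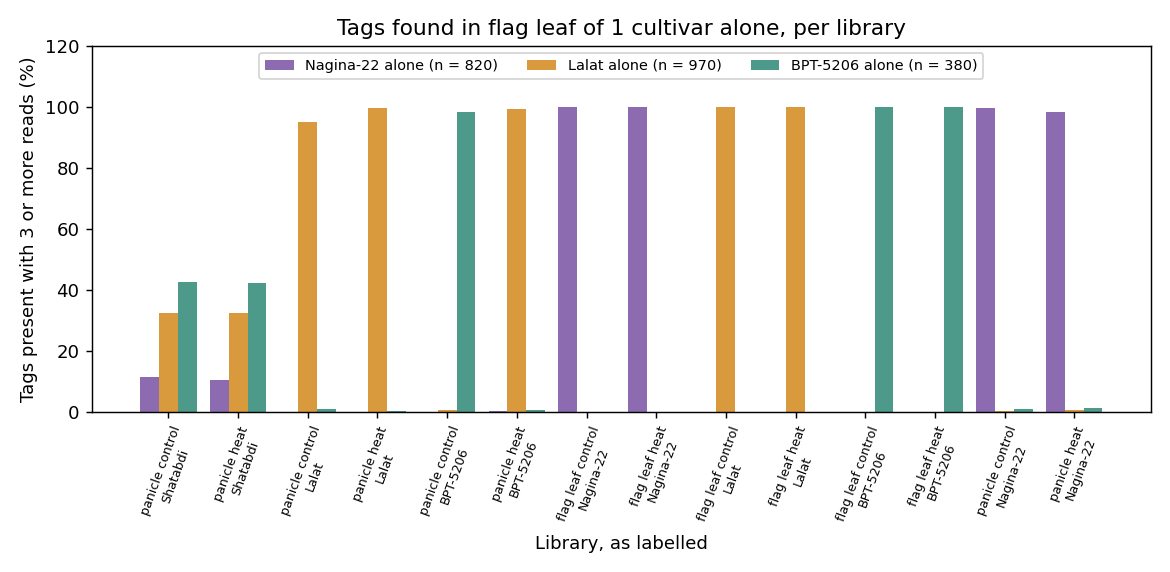
Share of tags present with at least 3 reads (percent, vertical axis) in each of the 14 libraries as labelled (horizontal axis); bars are the tags found in flag leaf of 1 of the 3 cultivars alone, 820 for Nagina-22, 970 for Lalat and 380 for BPT-5206. The library labelled panicle heat BPT-5206 stands at 99.3% for Lalat and 0.526% for BPT-5206. The control and heat libraries of Shatabdi, which has no flag leaf library, stand at 32.4% and 32.5% for Lalat and at 42.6% and 42.4% for BPT-5206.

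The series' title asks about modified miRNA ends and its design about heat, so length classes were compared first. Reads of 24 nt, the class of small RNAs that guide DNA methylation in plants, made 40.1% of reads of 20-26 nt in panicle and 21.8% in flag leaf. Their share was higher in panicle in 6 of 6 comparisons of 1 cultivar and condition, by 18.2 percentage points ± 4.61 (SD, n = 6; exact two-sided sign-flip permutation p = 0.0312, the smallest possible; adjusted p = 0.05 over 16 shares). The 6 comparisons come from 3 cultivars, and the permutation p values between tissues take the control and the heat comparison of a cultivar as independent. Reads of 21 nt, the length of most miRNAs, were lower in panicle in every comparison, by -7.82 points on average, and reads of 22 nt by -5.01 points. Heat moved the 24-nt share by -0.0574 points ± 5.83 (SD, n = 7 pairs; 3 of 7 higher; exact permutation p = 0.984). The mean change was 0.731 points ± 8.03 in panicle (n = 4) and -1.11 ± 1.49 in flag leaf (n = 3), and the difference between tissues gave an exact permutation p of 0.886. The spread of the pairs is far larger than the mean, so a heat change of a few points was not detectable with these 7 pairs.

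**Figure D2:**
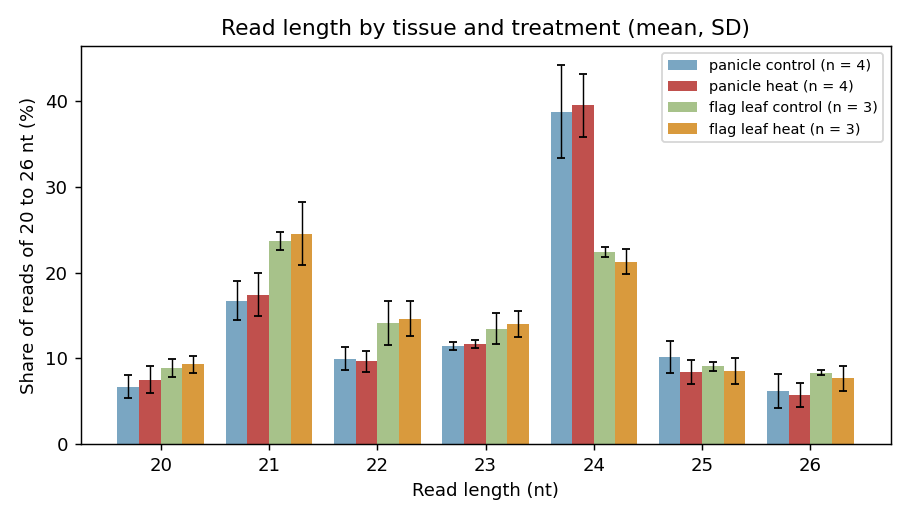
Share of reads of 20-26 nt (percent, vertical axis) at each length in nt (horizontal axis) for panicle and flag leaf under control and heat; bars are group means (n = 4 and n = 3) and error lines 1 SD. The 24-nt share of panicle control averaged 38.8% and that of flag leaf control 22.4%.

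Under heat over both tissues, miR168a-5p, which targets the silencing protein AGO1, had the smallest p: its log2 fold change was -0.63 (SE 0.21; edgeR adjusted p = 0.712), with lower values in 7 of 7 pairs. The next 5 were miR529b, which targets SPL transcription factors, at -0.68 (SE 0.32), miR820a, which targets the DNA methyltransferase DRM2, at -0.59 (SE 0.30), miR1876 at -0.47 (SE 0.25), the star strand miR168a-3p at -0.54 (SE 0.31) and miR166a-5p at -0.69 (SE 0.41), each with an adjusted p of 0.764. Copper miRNAs had positive values: miR398b, which targets Cu/Zn superoxide dismutase, 0.42 (SE 0.31), miR408-3p, which targets plantacyanin and laccase, 0.48 (SE 0.32) and miR528-5p 0.12 (SE 0.33). Among developmental miRNAs the miR166a-3p group, which targets HD-ZIP III factors, stood at 0.01 (SE 0.20), miR396e-5p, which targets growth-regulating factors, at -0.00 (SE 0.26) and miR159a, which targets GAMYB, at 0.07 (SE 0.25).

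Of the auxin list, miR167a-5p/167d-5p, which targets ARF6 and ARF8, stood at 0.15 (SE 0.29), miR160a at 0.11 and miR393a/393b-5p, which targets auxin receptors, at 0.03. Among nutrient miRNAs miR399d stood at -0.01, miR827 at 0.07 and miR399a at -0.63 (SE 0.54). Reproductive miR2275d, a trigger of phased siRNAs, stood at 0.37 (SE 0.41) and miR535-5p at -0.08. Of the rice-specific list, miR530-5p stood at -0.46 (SE 0.53), miR1425-5p at -0.21 and miR1432-5p at 0.07. In the silencing list miR162a, which targets DCL1, stood at 0.10 and miR390-5p, which triggers TAS3 siRNAs, at 0.02, and star strand miR408-5p stood at -0.03 (SE 0.67).

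No miRNA passed the test among 56 in edgeR (0 calls, 1 at an unadjusted p under 0.05; DESeq2 0 calls, 2 unadjusted). The median absolute log2 change was 0.18 and the median SE 0.32. In simulated counts of 53 miRNAs a log2 change of 1 was found in 3 of 4, and smaller changes were not simulated. Those counts held no differences between pairs, cultivars or tissues, so recovery in the real libraries may differ. miR1850.1, a rice-specific miRNA chosen after its values were seen, was called under settings that admit it: at log2 -5.26 without the low-count filter (adjusted p = 0.00577), at -5.43 without the flag leaf Lalat pair, at -5.26 without the flag leaf BPT-5206 pair and at -6.91 without the pairs with a length-limited file. Its reads numbered at most 25 in a library, and the fitted fold is no bound.

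By tissue, the smallest p values in panicle belonged to miR820a at log2 -1.06 (SE 0.34, adjusted p = 0.318), miR444b.1, which targets MADS-box factors, at -0.91 (SE 0.30), miR168a-5p at -0.81 (SE 0.28), miR166a-5p at -1.10 (SE 0.45), miR168a-3p at -0.79 (SE 0.43) and miR156a, which targets SPL factors, at -0.60 (SE 0.36). For miR820a the change was -1.92 in the pair labelled BPT-5206, whose heat library is in doubt, and -0.66 to -0.85 in the other panicle pairs. In flag leaf the order was different. There the smallest p values belonged to miR1876 at -0.77 (SE 0.36, adjusted p = 0.95), miR3979-5p at -1.69 (SE 0.83), miR2118o at 1.64 (SE 0.90), miR169f/169h, which targets NF-YA, at -0.79 (SE 0.43), miR167a-5p/167d-5p at 0.64 (SE 0.39) and miR408-3p at 0.79 (SE 0.50). Leading list members ran in panicle from -1.10 (miR166a-5p) to 0.65 (miR2275d) and in flag leaf from -1.13 (miR399a) to 0.79 (miR408-3p). The differences between tissues were led by miR444b.1 at -1.05 (SE 0.46, adjusted p = 0.768), miR820a at -1.10 (SE 0.51), miR169f/169h at 1.21 (SE 0.58), miR535-5p at -0.95 (SE 0.49), miR156a at -1.04 (SE 0.56) and miR2118o at -1.84 (SE 1.01), and leading list members ran from -1.44 (miR166a-5p) to 1.02 (miR2275d). None passed: edgeR gave 0 calls in panicle (4 unadjusted; DESeq2 0 and 3), 0 in flag leaf (0 unadjusted; DESeq2 0 and 2) and 0 for the difference (1 unadjusted; DESeq2 0 and 1). In panicle, miR1850.1 gave 1 call without the flag leaf BPT-5206 pair (log2 -7.41) and 1 without the pairs with a length-limited file (-7.56). Without TMM scaling the median of all miRNAs moved by 0.389 log2 in panicle, -0.182 in flag leaf, 0.575 for their difference and 0.151 over both tissues.

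No tested miRNA passed for a difference in heat response between heat-tolerant Nagina-22 and the susceptible cultivars. The smallest p values belonged to miR530-5p at log2 2.36 (SE 0.90, adjusted p = 0.451), miR3979-5p at 2.67 (SE 1.06), miR166e-3p at -3.76 (SE 1.54), miR166a-5p at 1.78 (SE 0.74), the miR166a-3p group at -0.81 (SE 0.36, adjusted p = 0.471) and miR396a-5p/396c-5p at -1.52 (SE 0.74). The value of miR166e-3p rests on the libraries with altered first nucleotides. It had 250 reads in flag leaf control Nagina-22, 381 in flag leaf heat BPT-5206 and at most 39 in any other library. Its log2 heat changes were -4.24 and 4.66 in the pairs of these libraries and at most 1.03 in the others. Leading list members ran from -1.87 (miR399a) to 2.36 (miR530-5p). In edgeR there were 0 calls (5 unadjusted; DESeq2 0 and 6). Leaving out the panicle Shatabdi pair gave 1 call (the miR166a-3p group, log2 -0.99), leaving out the flag leaf Lalat pair gave 1 (miR530-5p, 3.57), and leaving out the pairs with a length-limited file gave 1 (miR530-5p, 3.40). Without TMM scaling the median of all miRNAs moved by -0.733 log2 in this contrast, and 1 tolerant cultivar cannot part tolerance from genotype. The flag leaf pair of Nagina-22 joins a control library with altered first nucleotides to a length-limited heat file. Its panicle heat library held 42.6% of its reads at 35 nt.

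Irrespective of heat, Nagina-22 differed from the other cultivars in 3 miRNAs. miR1862d was higher at log2 1.63 (SE 0.28, adjusted p = 0.00231), with 4884 and 3294 CPM in its flag leaf libraries and 2145 and 2139 CPM in panicle. miR1883a was higher at 4.32 (SE 0.88, adjusted p = 0.00545), with 9.86 to 33.7 CPM in Nagina-22 libraries and at most 7.18 CPM elsewhere. These are 3 to 19 reads in each Nagina-22 library and at most 5 reads in any other, so the fitted fold is no bound. miR3979-5p was lower at -4.01 (SE 1.06, adjusted p = 0.0349). Copper miRNAs stood at 1.94 for miR398b (adjusted p = 0.0551), 2.22 for miR408-3p (0.0662) and 1.10 for miR528-5p (0.207). The star strands stood at 5.67 for miR408-5p, 2.32 for miR166a-5p and -1.19 for miR168a-3p. The value of miR408-5p rests largely on flag leaf heat Nagina-22, with 13718 reads. The other Nagina-22 libraries had 391, 99 and 8 reads, and libraries of other cultivars at most 206. miR168a-3p was counted from its listed start, whose full form had 5051 reads, against 303699 for a form that starts 3 nt later.

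Among the other leading members, development held the miR166a-3p group at -0.27, miR396e-5p at 0.25 and miR159a at -0.44; auxin held miR160a at 0.36, miR393a/393b-5p at 0.12 and miR167a-5p/167d-5p at -0.40; nutrient held miR827 at -1.13, miR399d at -0.78 and miR399a at -0.17. Reproductive miR2275d stood at 1.40, miR529b at -0.07 and miR535-5p at -0.65. Rice-specific miR530-5p stood at -1.47, miR1432-5p at 0.94 and miR1425-5p at 0.05. The silencing members miR390-5p, miR168a-5p and miR162a stood at 0.46, -0.18 and -0.12. The count of 3 calls among 56 (16 unadjusted) was 9 in DESeq2 and depended on single pairs: 11 without panicle Shatabdi, 7 without panicle Nagina-22, 2 without panicle BPT-5206, 2 without flag leaf Lalat, 2 without flag leaf BPT-5206 and 1 without flag leaf Nagina-22. The same test of each other cultivar against the rest gave 0 calls (9 unadjusted for Shatabdi, 5 for Lalat and 8 for BPT-5206). Libraries of 1 cultivar are not independent members of a tolerance class.

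Panicle and flag leaf differed widely in miRNAs. miR529b, a regulator of SPL factors, had the largest fold and was 797-fold higher in panicle (log2 9.64, SE 0.51, 12 libraries; edgeR adjusted p = 7.76e-09), with 227033 CPM ± 99404 (SD, n = 4) in panicle control against 245 ± 102 (n = 3) in flag leaf control. The triggers of phased siRNAs in reproductive tissue were higher as well: miR2118f at 7.12 (SE 0.74), with a ratio of 214 and a counting interval of 58.8 to 1779 from 2 flag leaf reads, miR2118a at 6.41 (SE 0.77), miR2275d at 5.66 (SE 0.67) and miR2118o at 4.37 (SE 0.59). miR2118e had 55 reads in the 6 panicle libraries compared and 0 in flag leaf, which makes it at least 26.1-fold higher against a floor of 3 counts over the group. miR319a, which targets TCP factors, rose 84.1-fold (log2 6.39, SE 0.56), miR166a-5p by 3.55 (SE 0.79), miR3979-5p by 3.37 (SE 0.56), miR399a by 2.14 (SE 0.80), miR390-5p by 1.70 (SE 0.32) and miR396e-5p by 1.57 (SE 0.31).

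Lower in panicle were rice-specific miR1432-5p at log2 -6.06 (SE 0.68) and miR1318-3p at -5.10 (SE 0.52). The listed miR1318-3p is the listed miR1432-5p shifted by 1 nt, so these falls are not separate evidence, though each counts as a call. Of the 4 copper miRNAs tested 3 fell: miR398b to -3.94 (SE 0.45), miR408-3p to -3.10 (SE 0.48) and miR528-5p to -2.57 (SE 0.47). The other, miR397a, was counted from few of its reads. Its listed form had 1588 reads over all libraries, and a form that starts 3 nt later, which was not counted, had 312828. This limit bears on the copper list in each comparison. miR398b stood at 69980 CPM ± 85346 (SD, n = 3) in flag leaf control and 5205 ± 4474 (n = 4) in panicle control. miR172a, which targets AP2-like factors, stood at -2.75 (SE 0.43), miR437 at -2.62 (SE 0.47) and miR168a-3p at -2.61 (SE 0.40). Next were miR159f at -2.12 (SE 0.55), miR169f/169h at -1.31 (SE 0.37), miR1876 at -1.30 (SE 0.31) and miR160f at -1.13 (SE 0.40). Counting shifted 5′ ends, miR168a-3p stood at -0.22 and passed no test, and its most-read form starts elsewhere than the listed one.

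Among leading list members with smaller folds, miR399d (1.16, SE 0.35), miR160a (0.95, SE 0.29) and the miR166a-3p group (0.65, SE 0.25) were higher. Lower were miR1425-5p (-1.04, SE 0.32), miR167a-5p/167d-5p (-0.88, SE 0.31) and miR168a-5p (-0.79, SE 0.27), all 6 at adjusted p values of 0.0118 to 0.034. Only reads at the listed start were counted, and the listed form of the miR166a-3p group made 68.4% of its reads in panicle and 40.3% in flag leaf. Its value of 0.65 therefore does not show a higher level of all miR166 reads. Values that did not pass over all miRNAs were 0.60 for miR393a/393b-5p, -0.05 for miR535-5p, -0.14 for miR530-5p, -0.35 for miR162a, -0.53 for miR159a, -1.15 for miR827 and -2.27 for miR408-5p. Of these, miR827 passed when adjusted over the nutrient list alone. In all, 35 of 55 miRNAs passed (37 unadjusted), 18 higher and 17 lower in panicle. DESeq2 gave 39 with 21 higher and 18 lower. Calls numbered 27 without the pair of the library labelled panicle heat BPT-5206. Without TMM scaling 36 passed with 10 higher and 26 lower, the median of all miRNAs moved by -0.78 log2 (DESeq2 0.182), and miR399a (1.30), miR390-5p (0.96) and miR396e-5p (0.71) no longer passed.

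**Figure D3:**
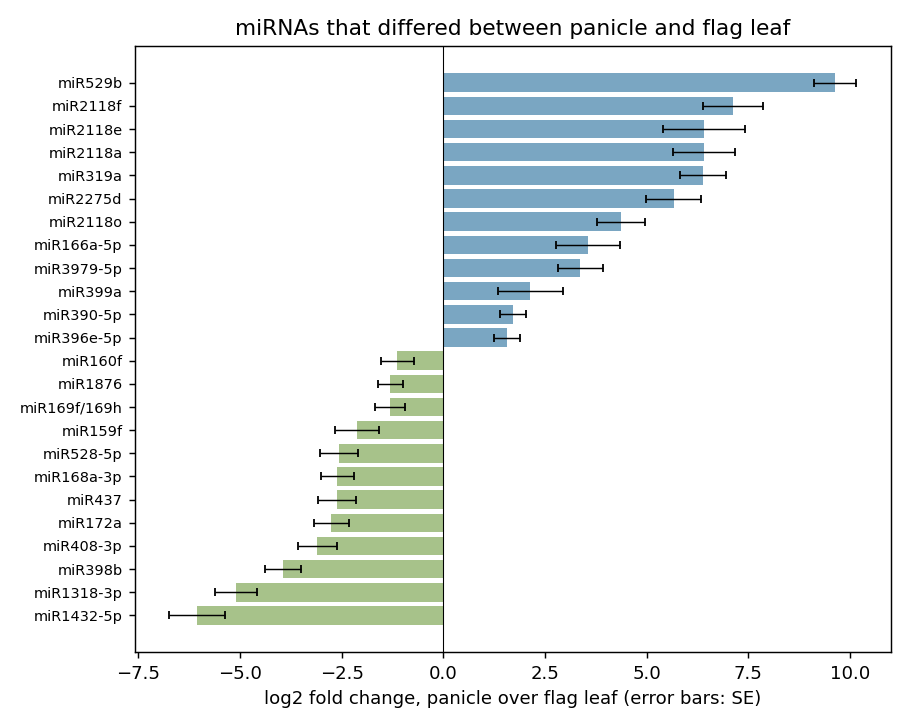
Fitted log2 fold change of panicle over flag leaf (horizontal axis) for the 24 named miRNAs (vertical axis); bars are fitted values over 12 libraries and error lines are 1 SE. miR529b stands at 9.64 and miR1432-5p at -6.06, and the bar of miR2118e, at 0 reads in flag leaf, is a fitted value and no bound.

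As groups, 6 of 7 tested reproductive miRNAs rose in panicle and 0 fell (adjusted over the list alone 6 and 0; median log2 6.41, and 5.66 with miR2118e at its bound; camera adjusted p = 0.00136, adjusted p = 0.0598 with an estimated correlation). Of 4 copper miRNAs 3 fell and 0 rose (3 adjusted over the list alone; median -2.83; camera adjusted p = 0.15, adjusted p = 0.745 with an estimated correlation; fry adjusted p = 0.00231). Rice-specific miRNAs gave 2 rises and 6 falls among 12, the same adjusted over the list alone (camera adjusted p = 0.43). The development list split into 5 rises and 4 falls of 18 (0.1 median, 0.11 mean, camera direction down, adjusted p = 1.00), the auxin list into 2 and 2 of 5 (0.905), the list of earlier heat reports into 6 and 7 of 22 (0.905), the star strands into 1 and 1 of 4 (0.905) and the silencing list into 1 and 1 of 3 (median -0.35, mean 0.19, adjusted p = 1.00), each count the same adjusted over the list alone. Nutrient miRNAs gave 2 rises and 0 falls of 3, and 2 and 1 adjusted over the list alone (0.905).

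Under heat, camera called the list of earlier heat reports upward (22 tested, 0 past the test, 0 adjusted over the list alone, median log2 0.10; adjusted p = 0.0222, adjusted p = 0.363 with an estimated correlation) and rice-specific miRNAs downward (12 tested, 0 and 0, median -0.47; adjusted p = 0.0222, adjusted p = 0.363 with an estimated correlation). miR168a-5p fell adjusted over the list alone in the silencing list (1 of 3; median 0.02, mean -0.17, camera down, adjusted p = 0.547). For the other lists, with 0 adjusted over the list alone, camera adjusted p values were 0.0691 for copper, 0.0993 for auxin and for star strands, 0.34 for reproductive, 0.417 for development and 0.779 for nutrient. In the heat contrasts of panicle, of flag leaf, between tissues and with tolerance no list was called (lowest camera adjusted p values 0.122, 0.0982, 0.504 and 0.17).

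For tolerance the copper list was called upward (4 tested, 0 past the test over all miRNAs, 3 adjusted over the list alone, median log2 1.70; adjusted p = 0.0385, adjusted p = 0.576 with an estimated correlation). Unscaled reads of miR398b were highest in flag leaf Nagina-22, at 84187 in control and 182826 in heat. In panicle they numbered 5724 and 1345 in Nagina-22, and 6463 and 11878 in susceptible Shatabdi. The call therefore does not show a rise over every susceptible cultivar in both tissues. The rice-specific list had 2 rises and 1 fall of 12, and 2 and 2 adjusted over the list alone (camera adjusted p = 0.886), the star strands 0 of 5, and 2 and 1 adjusted over the list alone (0.686). The other lists had 0 either way, with camera adjusted p values of 0.312 for development and nutrient, 0.852 for auxin, 0.886 for heat reports, 0.899 for reproductive and 0.899 for silencing (median -0.12, mean 0.05). Over 9 lists and 7 comparisons camera called 4, and 0 with an estimated correlation. Of these 4, fry called the reproductive list between tissues (fry adjusted p = 7.56e-07). It did not call heat reports (0.791) or rice-specific miRNAs (0.399) under heat, or copper for tolerance (0.155). Between tissues fry also called the copper list, the rice-specific list (0.00381) and the star strands (0.024). It called no list in the other comparisons.

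Beyond listed miRNAs, single sequences of 20-26 nt did change under heat, and the 5 largest rises among tags with a mean of at least 10 CPM belonged to 1 family. Of the sequences that begin TATCGAGTAGACCC, these 5 rose in 7 of 7 pairs: TATCGAGTAGACCCTGTCGTTA by log2 7.36 (SE 0.47, edgeR adjusted p = 0.00141), TATCGAGTAGACCCTGTCGTTGA by 6.95 (SE 0.50), with a mean of 2105 CPM, TATCGAGTAGACCCTGTCGTTAAA by 6.59 (SE 0.60), TATCGAGTAGACCCTGTCGTTAA by 6.55 (SE 0.53) and TATCGAGTAGACCCTGTCGTTGAC by 6.16 (SE 0.38). The largest falls at that mean, lower in 7 of 7 pairs each, were GTTTGGTGAATCGGAAACTTTTTTC, 1024 times higher in control from 3 heat reads (counting interval 350.1 to 4970), GTTTGGTGAATCGGAAACTTTTTTCA, 646 times higher from 2 heat reads (178 to 5340), TTCATGGACGTTGATAAGATCCTTC at -4.69 (SE 0.54), CTACATCTTGGCCCCTGCTCC at -4.60 (SE 0.49) and TTTCCTTGACTTCATAGAAC at -4.53 (SE 0.41). The 23-nt form of miR168a-5p, TCGCTTGGTGCAGATCGGGACCC, fell too (-2.49, adjusted p = 0.0287; chosen after its values were seen).

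Of 140024 tags tested, 132 passed (4350 unadjusted), 74 up and 58 down. Of the 74, 43 begin with the family's first 14 nt, and 57 hold most of these with a shifted start or an altered nucleotide allowed. DESeq2 called 420 with 230 up and 190 down. The count depends on single pairs: it was 29 without panicle Shatabdi, 54 without panicle Lalat, 87 without panicle BPT-5206, 59 without flag leaf Nagina-22, 32 without flag leaf Lalat, 54 without flag leaf BPT-5206 and 164 without panicle Nagina-22, where the balance turned to 63 up and 101 down. With the 4 pairs of full-length files alone it was 0 (3424 unadjusted), though the named tags kept their directions.

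Summed over its 75 tags, of which single ones fell in some pairs, the family rose 21.1-fold in panicle Lalat, from 807 to 17006 CPM, 10.9-fold in panicle Nagina-22, 9.17-fold in the panicle BPT-5206 pair, 7.98-fold in Shatabdi, 5.17-fold in flag leaf Nagina-22, 4.28-fold in flag leaf BPT-5206 and 3.17-fold in flag leaf Lalat, where it went from 10938 to 34695 CPM. The mean log2 rise was 2.88 ± 0.92 (SD, n = 7; exact permutation p = 0.0156, the smallest possible). The level of the family, over control and heat, was lower in panicle than in flag leaf by log2 -1.69 ± 1.14 (SD, n = 6; 0 of 6 higher; exact permutation p = 0.0312, the smallest possible). The family was chosen after its values were seen. Tags were not sorted by class of RNA, so whether the family is a small RNA or a fragment of chloroplast or other longer RNA was not determined.

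**Figure D4:**
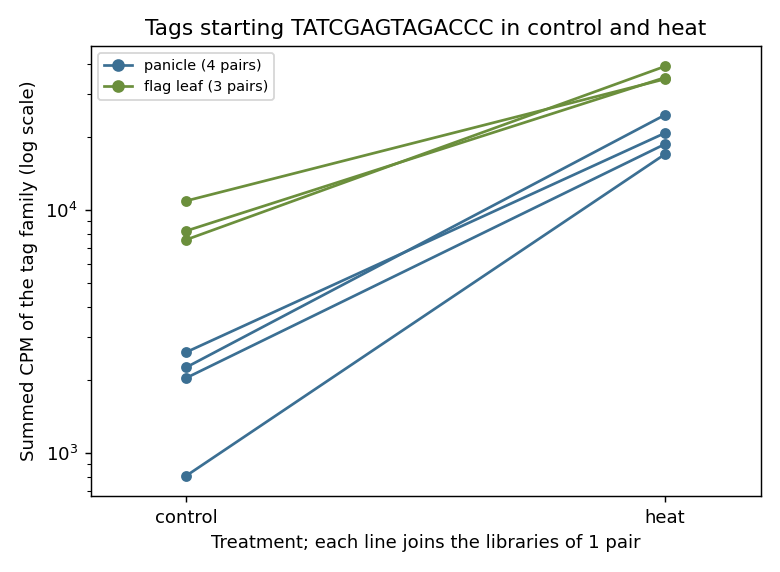
Summed CPM (log axis) of the family of 75 tags that begin TATCGAGTAGACCC, in control and heat libraries joined by a line for each of the 7 pairs. Every line rises, from 807 to 17006 CPM in panicle Lalat and from 10938 to 34695 CPM in flag leaf Lalat.

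The 3′ ends of that family and of miR168a-5p differed under heat as well, in tests chosen after the values were seen. Family sequences with T after position 22 made 85.2% ± 6.90 of the family in panicle control and 30.0% ± 12.9 in panicle heat (SD, n = 4), and 94.4% ± 1.03 and 47.0% ± 19.3 in flag leaf (n = 3). Those that end at 22 nt went from 7.49% to 31.0% and from 2.54% to 29.5%, and those with A after position 22 from 2.80% to 26.3% and from 0.426% to 9.31%. These are shares of a family whose sum rose, and the normalised CPM of the sequences with T after position 22 was itself 1.12-fold (flag leaf Lalat) to 8.84-fold (panicle Lalat) higher in heat in 7 of 7 pairs. Per read of all tags it was higher in 6 of 7, with flag leaf Lalat at 0.962-fold. The 24-nt form of miR168a-5p went from 34.7% to 20.99% in panicle and from 20.9% to 14.3% in flag leaf, and the 22-nt form from 13.3% to 22.1% and from 12.3% to 18.96%. Each of these shares moved the same way in 7 of 7 pairs (exact permutation p = 0.0156, the smallest possible). The 21-nt form of miR168a-5p, at 47.0% and 53.2% in panicle, was higher in 5 of 7.

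**Figure D5:**
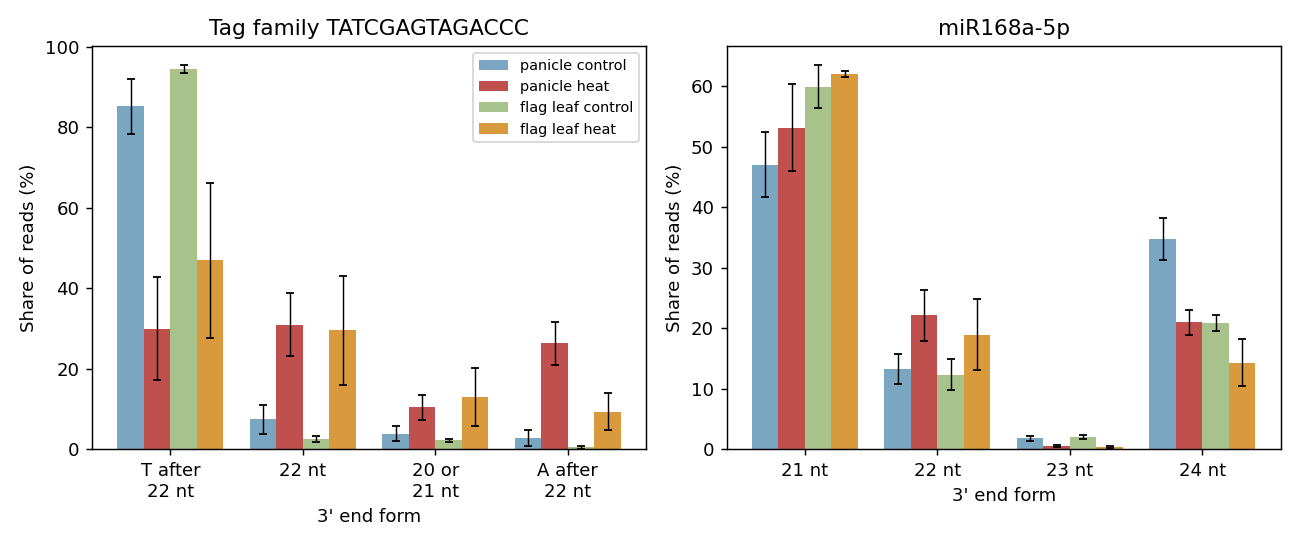
Share of reads in percent (vertical axes) of each 3′ end form (horizontal axes) of the tag family and of miR168a-5p by tissue and treatment; bars are group means (n = 4 in panicle, n = 3 in flag leaf) and error lines 1 SD. Family sequences with T after position 22 averaged 85.2% in panicle control and 30.0% in panicle heat, and 24-nt miR168a-5p averaged 34.7% and 20.99%.

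Between tissues, single sequences differed on a large scale, and the share of tags higher in panicle was largest at 24 nt. Of the 24-nt tags 48.9% were higher and 6.84% lower in panicle, against 44.6% and 17.2% at 23 nt, 36.4% and 24.2% at 21 nt and 16.7% and 39.9% at 26 nt. Among tags with a mean of at least 10 CPM the largest rises were 24-nt tags with 0 reads in flag leaf, so that each is a lower bound against a floor of 3 counts over the group: AGGACATAGGCTTGACATAAGACG at least 1089-fold higher, AGGACATGTTGATTGTAATTGGCC at least 1074-fold, AGAGGCACTCGTAGGCTGCAATGG at least 1071-fold, GGGACCAGTAGACGTCATCAGCGT at least 1041-fold and ATCTGAGATCAGACTTTGGACGCC at least 317-fold. This last tag stood at 63.9, 56.9 and 34.3 CPM in 3 of the 6 panicle libraries compared and at 0 to 0.112 CPM in the other 3. The largest falls at that mean were TGGCGCTGTGGGATGAACCA, with 0 reads in the 6 panicle libraries compared and at least 819-fold lower there, though read at 0.101 and 0.0884 CPM in the Shatabdi libraries, which were not compared. Others were altered forms of miR397 and miR166: TTTAGTGCAGCGTTGATGAACC, 25349 times lower from 2 panicle reads (counting interval 7017 to 209322), TGGAGTGCAGCGTTGATGAACC, at least 5915-fold lower, GTGAGTGCAGCGTTGATGAACC at log2 -11.88 (SE 2.24) and TTCTGACCAGGCTTCATTCCC at -11.39 (SE 3.81). These last 4 are read mostly in the pair of flag leaf libraries with altered first nucleotides, which hold 99.8% to 99.9% of their CPM. In all, 79734 of 140024 tags passed (85854 unadjusted), 57982 higher and 21752 lower in panicle, and 68984 without the panicle BPT-5206 pair. With 50 reads required in 3 libraries 16472 passed, of fewer tested tags. Without the pairs with a length-limited file, which include both libraries with altered first nucleotides, 40716 passed.

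Ends of miRNAs were compared next, since modified ends are the title's subject. Reads with nucleotides at the 3′ end that the listed sequence does not explain made 44.0% ± 7.68 (SD, n = 14 libraries) of miR168a-5p reads, 12.2% ± 4.30 of miR408-3p reads and 8.59% ± 3.29 of miR159a reads. Lower shares were found for miR396e-5p (3.61%), miR166k-3p (2.51%), miR396a-5p/396c-5p (1.80%), miR444a-3p.2 (1.42%), miR1425-5p (1.14%), miR398b (1.01%) and the miR166a-3p group (0.299%). For comparison, mismatches inside the miRNA made 0.0485% to 0.113% per position in group means, and mismatches at the last position, which count as tailed here, 0.339% to 0.432%, above the share of the miR166a-3p group. The median share over miRNAs was 3.39% ± 0.619 in panicle control, 3.95% ± 0.518 in panicle heat (n = 4 each), 4.31% ± 0.240 in flag leaf control and 5.49% ± 0.558 in flag leaf heat (n = 3 each).

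In heat this share was higher in 6 of 7 pairs, by 0.826 percentage points ± 0.607 (SD, n = 7; exact permutation p = 0.0312, adjusted p = 0.25 over 16 shares), which fails the correction. It was 0.110 points (exact permutation p = 0.359) when only nucleotides beyond the mature length counted, and it was reversed, at -0.622 points (exact permutation p = 0.0469), when all miRNA reads were pooled. The heat change was 0.566 points in panicle and 1.17 in flag leaf, and their difference gave an exact permutation p of 0.229. Among tails of 1 nt, T made 24.9% in control and 29.0% in heat, higher in 7 of 7 pairs by 4.05 points ± 2.27 (SD, n = 7; exact permutation p = 0.0156, the smallest possible; adjusted p = 0.25). Tails of miR168a-5p weigh heavily in these shares, and without it T made 45.3% in panicle control and 54.3% in panicle heat, 38.8% and 47.4% in flag leaf, higher in 6 of 7 pairs by 8.87 points ± 6.75 (exact permutation p = 0.0312; chosen after the values were seen).

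In panicle the tailed share was lower than in flag leaf in 6 of 6 comparisons, by -1.09 points ± 0.489 (SD, n = 6), and the share of reads shortened at the 3′ end was higher in 6 of 6, by 0.729 points ± 0.356. Among tails of 1 nt, A made 10.97% in panicle against 17.7% in flag leaf (higher in 0 of 6) and G made 4.50% against 1.92% (higher in 6 of 6). Each gave an exact permutation p of 0.0312, the smallest possible, and an adjusted p of 0.05 over 16 shares. Without miR168a-5p, A made 21.2% in panicle control and 36.6% in flag leaf control (higher in 0 of 6), and G made 9.69% and 3.87% (higher in 6 of 6).

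For single miRNAs under heat, miR394, which targets an F-box gene of meristems, had more tailed reads: 1.72% ± 0.863 to 3.46% ± 2.14 in panicle (SD, n = 4) and 1.86% ± 0.745 to 6.13% ± 3.55 in flag leaf (n = 3), higher in 7 of 7 pairs (log2 ratio 1.16, SE 0.28; limma adjusted p = 0.048). Next were miR1432-5p at -0.95 (SE 0.32, adjusted p = 0.18), miR444d.3 at -0.98 (SE 0.39, adjusted p = 0.252) and miR390-5p at 0.57 (SE 0.24, adjusted p = 0.252). Of the 10 miRNAs of most reads, miR168a-5p stood at -0.25 (SE 0.19), miR396e-5p at 0.33 (SE 0.25), miR444a-3p.2 at 0.17, miR398b at -0.13, miR396a-5p/396c-5p at -0.07, miR159a at -0.05, miR166k-3p at 0.04, miR408-3p at 0.03, the miR166a-3p group at -0.02 and miR1425-5p at 0.01. miR394 was the 1 call among 28 miRNAs (4 unadjusted). It passed without the panicle BPT-5206 pair and in 0 of the other 6 fits that leave out a pair, and when only altered nucleotides within the mature length counted its value was reversed, at -0.41.

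Between tissues, tailing was higher in panicle for miR160a, which targets ARF10 and ARF16 (48.1% ± 7.73 of reads in panicle control against 20.2% ± 4.56 in flag leaf control; log2 ratio 1.999, SE 0.21), for miR171b, which targets GRAS factors (1.79, SE 0.26), miR1862d (1.01, SE 0.33), miR1432-5p (0.94, SE 0.34), miR408-3p (0.70, SE 0.24) and miR168a-5p (0.64, SE 0.20). It was lower for miR535-5p (-1.18, SE 0.28), miR393a/393b-5p (-0.67, SE 0.20) and miR162a (-0.60, SE 0.18). Of the 10 miRNAs of most reads, the others stood at -0.61 for miR159a (SE 0.27), -0.41 for miR396e-5p, -0.41 for miR166k-3p, -0.22 for the miR166a-3p group, 0.02 for miR396a-5p/396c-5p, 0.12 for miR398b, 0.32 for miR444a-3p.2 and 0.37 for miR1425-5p. These 9 are the calls among 25 miRNAs (limma; 11 unadjusted). When only nucleotides beyond the mature length counted, 1 passed, and the signs of miR160a (-1.62) and miR393a/393b-5p (0.27) were reversed. With altered nucleotides within the mature length alone, 4 passed, and miR171b (-0.46), miR168a-5p (-0.55) and miR408-3p (-0.85) were reversed. Leaving out a pair gave 2 for panicle Lalat, 5 for panicle BPT-5206, 6 for flag leaf Nagina-22, 2 for flag leaf Lalat, 4 for flag leaf BPT-5206 and 3 for panicle Nagina-22. Forms of related loci are not separable here from tails, which bears on miR160a, miR171b and miR1862d. The form of miR1432-5p with an added A, at 8411 reads, ends as the listed miR1318-3p does, so this A may be encoded rather than a tail.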

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

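The tests of a wrong label and of mixed RNA for the library labelled panicle heat BPT-5206, that of a 5′ modification in 2 flag leaf libraries, those of tags that end in AG and the splits by cultivar were chosen only after the result was seen. Values far from the rest of their group were sought in 76 groups of 4 libraries and found in 7. Chance flags about 1 in 20 groups.

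The 24-nt share of panicle control Nagina-22 was 46.9%, against 35.1% to 36.5% in the other 3 panicle control libraries. In panicle control Shatabdi, miR2118e stood at 84.2 CPM (others 1.98 to 14.2), miR3979-5p at 1539 CPM (others 10.7 to 215) and miR396e-5p at 284461 CPM (others 75267 to 89300). In panicle heat Shatabdi, miR528-5p stood at 2536 CPM against 464 to 712 in the other 3. In panicle heat Nagina-22, the median share of reads starting inside the listed 5′ end was 0.350% against 0.115% to 0.143%, and miR1883a stood at 9.86 CPM, from 3 reads, against 0 in each of the others. Reads identical to animal miRNAs, a signal outside the rice miRNAs, numbered 26475 in panicle control Lalat (1778 CPM of reads of 20-26 nt), 156 in flag leaf control Nagina-22 (23.05 CPM) and 221 in flag leaf heat BPT-5206 (24.4 CPM).

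The library labelled panicle heat BPT-5206 held 99.3% of the 970 tags found in flag leaf of Lalat alone, close to the 99.5% and 95.1% of the Lalat panicle libraries. The other panicle libraries held at most 0.515%, apart from those of Shatabdi, which has no flag leaf library, at 32.4% and 32.5%. The library held 0.526% of the 380 tags found in flag leaf of BPT-5206 alone, of which panicle control BPT-5206 held 98.4% and those of Shatabdi 42.6% and 42.4%, and this argues against a mixture of RNA of both cultivars. The Lalat panicle heat library stored under both labels is argued against by the miRNA counts, which differed by a chi-square per degree of freedom of 95.4, far above sampling noise. What stays open is a library of Lalat that carries the wrong label, with which the 99.3% is consistent. No partner out of place was found among the libraries of BPT-5206.

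Altered first nucleotides were seen on a median of 5.38% of reads per miRNA in flag leaf control Nagina-22 and 4.86% in flag leaf heat BPT-5206, and these 2 libraries also hold the altered forms of miR397 and miR166 that fall in the tissue comparison of tags. A 5′ modification set by heat, cultivar or tissue alone is argued against, since the highest share in the other 12 libraries was 0.00695 of the lower of these 2, and the flag leaf libraries of the same cultivars in the other condition, heat Nagina-22 and control BPT-5206, had a median of 0%. Panicle control Nagina-22, of the same cultivar and condition as the first of the 2, also had a median of 0%. A modification set by tissue, cultivar and condition together stays open, since each such combination has a single library. Errors in the first sequencing cycles may be the source: abundant tags that are no listed miRNA carried altered first nucleotides at 47.7 times or more the median of the rest (4.92% and 5.34% against 0.103%). Chemistry or trimming specific to these libraries was not tested.

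Of the 58 tags that fell in heat, 23 end in AG (39.7%, against 3.995% of all tags; Fisher's exact p = 1.48e-17, with overlapping tags that are not independent), and 5 carry a CTNAY motif ahead of the AG, as intron 3′ ends do. Loss of any tag that ends in AG, as the whole cause, is argued against. It needs such tags to fall as a set. The 23, whose log2 changes ran from -7.36 to -3.86, were picked by their falls, so they do not set the size of that fall. All 5594 tags that end in AG had a median log2 change of 0.0465 (SD 0.83), and their summed reads a mean of 0.03 (SD 0.41 over 7 pairs). Their summed reads were lower in heat in 5 of 7 pairs, so a small fall of such tags is not excluded. An earlier criterion, replaced after its outcome was seen, had left this open: the 5084 without the motif were lower in 5 of 7 pairs (exact permutation p = 0.812), with a median of 0.05 that was as low in 1906 of 10000 random lists of tags. Loss of intron 3′ fragments stays open, since a tag can carry the motif without coming from an intron. The test first planned, on tags outside the calls, decides nothing, since it leaves out the tags that fell. The summed reads of all 510 tags with the motif were lower in heat in 4 of 7 pairs (exact permutation p = 0.688), yet their median log2 change of -0.01 was as low in 66 of 10000 random lists. A change in intron turnover for single transcripts was not tested.

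Chance was weighed by giving the labels to the libraries in other ways. Where the real count is 0, every split gives at least as many, so the outcome is fixed and says nothing about chance. This holds for miRNAs under heat (64 of 64 splits, highest other 2), for the heat-by-tissue difference (35 of 35, highest other 2), for the heat-by-tolerance difference (21 of 21, highest other 0), in panicle (8 of 8, highest other 1) and in flag leaf (4 of 4, highest other 1). A chance effect can be excluded at a share under 0.05 for tags under heat (132 calls, 1 of 21 splits drawn, highest other 2). For tailing under heat it cannot (1 call, 4 of 64 splits, highest other 1).

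Between tissues, 1 of 32 splits gave as many calls for miRNAs (35 calls, highest other 0), 1 of 32 for tailing (9 calls, highest other 2) and 1 of 21 splits drawn for tags (79734 calls, highest other 68). These splits take the control and the heat comparison of a cultivar as independent. With cultivars as the units there are 4 splits, too few for a share under 0.05 (highest other 0 for miRNAs, 0 for tailing and 43 for tags). For tolerance, 2 of 100 splits drawn gave as many calls (3 calls, highest other 6), but these splits deal out single libraries. By cultivar there are 4 splits as well, too few for a share under 0.05 (3 calls, highest other 0).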

How the results depend on the processing

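The alternatives named here as without length-limited pairs, with every miRNA, with altered nucleotides within the mature length, with 18-26 nt and with an estimated correlation were chosen after seeing the data. For each result below the cause was not tested, except that fewer pairs or tags were tested where these were left out. Calls for miRNAs under heat moved from 0 to 1 without the low-count filter, to 1 without length-limited pairs and to 0-1 when a pair was left out; in panicle to 1 and 0-1; for heat by tolerance to 1 and 0-1. Calls for tolerance (3) became 9 in DESeq2, 8 without the filter, 1 with exact reads, 9 without length-limited pairs and 1-11 without a pair. Tag calls under heat (132) became 420 in DESeq2, 85 with 50 reads required, 0 without length-limited pairs and 29-164 without a pair; with no replicate block they were 134. Tag calls between tissues (79734) became 16472, 40716 without length-limited pairs. The 24-nt share difference in heat (-0.0574 points) became 1.45 for distinct sequences, 0.657 within 15-30 nt, 0.755 within 18-26 nt, 0.548 without length-limited pairs and -1.28 to 1.62 without a pair. The tailed share difference (0.826 points) became 0.123 with altered nucleotides within the mature length, 0.420 with every miRNA, 0.110 with added nucleotides alone, -0.622 (reversed) pooled and 0.690-0.979 without a pair. Tailing calls in heat (1) became 0 with either tail definition, with every miRNA, with no replicate block and with a prior of 2, and 0-1 without a pair; between tissues (9) they became 4 with altered nucleotides within the mature length, 1 with added nucleotides and 2-6 without a pair. Camera calls (4) became 0 with an estimated correlation.

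Reversed were, with added nucleotides alone, miR160a (-1.62) and miR393a/393b-5p (0.27), and, with altered nucleotides within the mature length, miR394 (-0.41), miR171b (-0.46), miR168a-5p (-0.55) and miR408-3p (-0.85). For numbers of miRNAs and tags, the fit with no replicate block was run for miRNAs under heat, within each tissue and between tissues, and for tags under heat. It changed no number of calls there beyond 1.5 times, with 33 miRNA calls between tissues. Of 331 values of named miRNAs between tissues 297 kept direction and call and 34 lost the call; of 120 values of named tags in heat 103 kept both and 17 lost the call. miR1850.1 had at most 25 reads in a library, and the effect of depth was not tested.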

Other observations

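The tests of isomiR shares, of the family's ends and of miR168a-5p ends were chosen only after the result was seen. Forms of 1 miRNA that differ at an end differed between panicle and flag leaf in the same direction in every comparison for 42 of 125 forms of 37 miRNAs, where chance gives 3.91, and for 46 in the 5 comparisons left without the library labelled panicle heat BPT-5206, where chance gives 7.81. Leaving a comparison out cannot lower the count, so the 46 does not test that library. The 22-nt form of miR167, TGAAGCTGCCAGCATGATCTGA, made 43.3% of that miRNA's reads in panicle and 80.4% in flag leaf (-37.1 points ± 9.45, SD, n = 6; exact permutation p = 0.0312, the smallest possible), and the 21-nt form TGAAGCTGCCAGCATGATCTG made 51.7% and 12.1%. This 21-nt sequence is listed as miR167d-5p, which is joined here with miR167a-5p. Of miR166, the form that starts 1 nt earlier, TTCGGACCAGGCTTCATTCCC, made 21.8% in panicle and 44.5% in flag leaf, against 68.4% and 40.3% for the listed form. The earlier start of miR156a, TTGACAGAAGAGAGTGAGCAC, made 73.9% and 88.9%. Within the joined miR396a-5p/396c-5p, the 21-nt sequence TTCCACAGCTTTCTTGAACTG made 27.3% and 0.898%. That sequence is listed as miR396a-5p, so this is a share between listed miRNAs rather than an end variant of 1. Only 1 of 32 splits gave as many forms (42 real, highest other 7), with the control and the heat comparison of a cultivar taken as independent. By cultivar there are 4 splits, too few for a share under 0.05 (highest other 6). Forms of related loci could contribute, since loci were not separated here.

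In heat, 12 of 125 forms moved the same way in 7 of 7 pairs, where chance gives 1.95 (1 of 64 splits, highest other 9, so a chance effect can be excluded at a share under 0.05 with every pair as labelled). In the 6 pairs left without that of the library labelled panicle heat BPT-5206 these 12 remained, where chance gives 3.91. Leaving a pair out cannot lower this count, so it does not test that library, and the splits were not repeated without it. Forms of miR168a-5p make 3 of them. The T-tailed form of miR394 went from 0.757% to 3.33% over all pairs, and the 21-nt form of miR167 from 32.2% to 39.3%. The miR319a form CTTGGACTGAAGGGTGCTCCCT went from 51.0% to 38.3%, the 24-nt form of miR1862d from 63.3% to 70.0% and the 23-nt form of miR820a from 12.8% to 8.94%, each the same way in 7 of 7 pairs (exact permutation p = 0.0156, the smallest possible).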
